A study of Mus musculus with 4 samples.

How the data were processed

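The series held 4 RNA sequencing libraries of mouse 2-cell embryos, 2 from embryos cultured with dTAG-13 and 2 from embryos cultured with DMSO, each made from a pool of 3 embryos. Per the labels' protocols, the libraries were prepared from polyadenylated RNA with the SMART-seq v4 kit and were not stranded. Groups and replicate numbers were taken from the sample labels, and the columns of the tables were matched to samples by the treatment and number in their names. The labels do not say that the 2 pools of a group came from different parents or days, so p-values measure only the spread between these pools, which may be technical.

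The files were a table of scaled reads for 18714 genes and a table of the authors' own comparison. Per the submitters' processing notes the tools were bcl2fastq, Picard, HTSeq and DESeq, without versions, and the genome build was mm10; the aligner and the annotation release are not given in the sources used here. The deposited signal values are reads per gene that the authors divided by a size factor per library. Each value was a whole multiple of the column's smallest value above 0, so whole reads were recovered for 100% of values within a tolerance of 1e-04 reads. Recovered totals were 38112685 and 33897568 reads for the dTAG-13 libraries and 18923479 and 16522506 reads for the DMSO libraries, and all gene rows had a name. A gene without a read in a library may have up to 3 reads by counting error, or 1.87 and 2.09 scaled reads in the dTAG-13 libraries and 3.60 and 4.87 in the DMSO libraries. Ratios with few reads in 1 group were given a 95% exact binomial interval; floors and intervals cover counting error only.

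In the authors' deposited table, which lists 16281 genes whose mean reached 15.0 scaled reads in at least 1 group, each gene has a p-value and an adjusted p-value of the treated against the DMSO group. The deposited log2 values are the authors' log2 ratios of treated over DMSO, which equal the log2 ratios of the deposited group means where both are above 0; where 1 mean is 0, they equal the log2 ratio with 1 added to each mean. The adjusted p-values were computed by the authors over the 18714 genes of the scaled table. No standard error or number of replicates accompanies these values.

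The main test was fixed before the data were examined. Scaled reads were transformed to log2(value + 1), genes with a mean of at least 10 scaled reads over the 4 libraries were kept (15978 genes), and the groups were compared with limma 3.58.1 in R 4.3.3 by lmFit and eBayes with a mean-variance trend, two-sided. Adjusted p means the Benjamini-Hochberg value over all genes tested unless a list alone is named, and a gene counted as higher or lower at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which can differ from the ratio of the group means in either direction for genes with a library at or near 0 reads. Each fold change is given with its standard error from the fit, and each mean with the SD of 2 libraries.

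Also fixed before the data were examined were 27 gene lists and the rule for naming genes. The lists covered NELF subunits, pause release and elongation factors, 2-cell transient genes, oocyte transcripts, maternal mRNA decay factors, ribosome biogenesis, ribosomal proteins, translation factors, proteasome subunits, the spliceosome core, RNA polymerase II and general factors, mitochondrially encoded genes, nuclear oxidative phosphorylation, replication-dependent histones, DNA replication, G2 and mitosis, p53 targets, immediate early genes, heat shock, the integrated stress response, preimplantation lineage factors, methylation enzymes, Y-linked genes, and markers of cumulus and granulosa cells, sperm, oviduct epithelium and blood. Lists with at least 5 tested members were compared with all other genes by camera in limma with a preset correlation of 0.01 and adjusted over 26 lists. Of these, 14 lists passed, 9 up and 5 down. With a correlation estimated from the data 0 lists passed, and the smallest adjusted p was 0.333. That version of camera takes its degrees of freedom from the few libraries, so hardly any list could pass. For the 2-cell transient genes the estimated correlation was -0.0037, below the preset, yet the unadjusted camera p rose from 6.8e-06 to 0.0373. For that list the loss therefore does not show that correlation among members removed the call. Other lists had estimated correlations far above the preset, among them ribosome biogenesis (0.463), oocyte transcripts (0.215) and mitochondrially encoded genes (0.983). There correlation among members may have removed the call, and its share was not separated from that of the few libraries. Genes named in the text are the 4 NELF subunits, the 10 highest and 10 lowest fold changes among genes past the threshold with a mean of at least 100 scaled reads and no overlap between groups (without predicted genes, clone names and pseudogenes, and with at most 2 genes of a family), and up to 4 members of each list with the smallest p. Any other gene is said to have been chosen after its value was seen.

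Gene positions and exon counts were taken from GENCODE M21 on GRCm38, the assembly called mm10, in which 15917 of the 15978 tested genes were found by identifier; Rasgef1b was among those not found. Because the libraries were not stranded, overlapping genes cannot be told apart where they share sequence: 251 tested genes had at least 50% of their exonic bases within exons of other genes, and among the 126 named genes only Adat3 did. Members of multigene families with near-identical copies, such as the Tcl1b, Zscan4, Tcstv, Usp17l, Oog and Tdpoz genes, may exchange reads, and how the authors counted such reads is not given in the sources used here.

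A chi-square statistic of the recovered reads between the 2 libraries of a group averaged 90.7 per gene for dTAG-13 and 104 for DMSO, which does not separate technical from biological spread. The libraries were treated as separate samples because the labels list them as such. The fit was tested on simulated reads for 15978 genes drawn from a negative binomial with the means, depths and trended dispersions of these 4 libraries, with 200 changed genes. limma found 4% of 50 genes changed 2-fold, 46% of 50 changed 4-fold, 82% of 50 changed 8-fold and 84% of 50 changed 16-fold, and called 7 of 15778 unchanged genes. In a second simulation camera passed a list of 40 genes changed 4-fold and 0 of 50 unchanged lists. In both simulations the changed genes came only from genes with a mean of at least 100 scaled reads, as did the unchanged lists. Each gene took the trended dispersion of its level, without a spread of its own. Recovery was therefore not measured below that mean. Neither recovery nor false calls were measured for genes with a spread wider than the trend. Genes were drawn independently of each other in both simulations. The second therefore does not show how camera with the preset correlation behaves for lists whose members move together.

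Alternatives fixed beforehand were edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, pseudocounts of 0.5 and 10, no low-value filter and means of at least 50 and 100, scaling to equal totals, to quantiles, to the oocyte transcripts, to the mitochondrially encoded genes and by TMM, no variance trend, robust variances, the replicate number as a block, an adjusted p under 0.1, an absolute log2 fold change of at least 1, leaving out each library in turn, and the authors' deposited calls. Thinning of all libraries to the smallest depth was added after the depths were seen. No per-sample column was left out.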

Results

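RNA sequencing was performed on mouse embryos at the 2-cell stage in which both copies of Nelfb carried a degron tag. Nelfb encodes a subunit of negative elongation factor (NELF), a protein complex that holds RNA polymerase II paused shortly after it has begun transcription. Zygotes from natural matings of homozygous parents of an outbred ICR background were cultured for 30 hours in KSOM embryo medium with either 500 nM dTAG-13, a small molecule that brings the tagged protein to a ubiquitin ligase for degradation, or 0.01% DMSO as the vehicle. Each library was made from the polyadenylated RNA of 3 embryos, and each group had 2 libraries. The dTAG-13 libraries held 38112685 and 33897568 reads in genes, and the DMSO libraries held 18923479 and 16522506, so that 1 read was worth 0.622 and 0.697 scaled reads in the dTAG-13 libraries and 1.20 and 1.62 in the DMSO libraries. Across the 15978 genes tested, which are not independent replicates, Pearson's r between log2 values was 0.866 for the dTAG-13 libraries and 0.791 for the DMSO libraries, and it lay between 0.637 and 0.718 for the 4 pairs across groups. The first principal component held 60.1% of the variance and separated the groups.

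To describe the tagged gene and its partners in every library, the mRNA of the 4 NELF subunits was compared. Nelfb (ENSMUSG00000013465.18, chromosome 2, 25199712 to 25211489 in GRCm38, 13 annotated exons) had 63.4 and 35.6 scaled reads in the dTAG-13 libraries and 182.5 and 69.8 in the DMSO libraries. Its log2 fold change of -1.23 ± 0.86 (SE, n = 2 per group) did not pass the test (adjusted p = 0.343, limma). It was -0.54 without DMSO replicate 1 and -1.92 without DMSO replicate 2, and it turned to 1.11 with libraries scaled on the oocyte transcripts (adjusted p = 0.366). The degrader acts on protein, so the mRNA level does not check the group labels. Nelfe (chromosome 17, 34850391 to 34856372), the subunit with an RNA recognition motif, rose by 4.30 ± 0.69 on the log2 scale, from 299.2 ± 251.0 to 4773 ± 199 scaled reads (mean ± SD, n = 2; adjusted p = 0.0258), and was the 1 subunit of 4 that passed over all genes. Nelfcd (chromosome 2, 174415804 to 174427502) had 738.4 and 472.8 scaled reads with dTAG-13 against 46.8 and 0 with DMSO. Its log2 fold change of 6.42 ± 1.92 did not pass over all genes (adjusted p = 0.0741, limma). The size of this value rests on the library at 0, although the other DMSO library also lay below both dTAG-13 libraries. The authors' deposited log2 ratio was 4.69 (adjusted p = 0.191 in their test). Over all genes, 2 of the 4 subunits were higher with DESeq2, a pseudocount of 10, a mean of at least 50 and the replicate block, and 1 was higher with edgeR. With p adjusted over the list alone, 2 of the 4 subunits were higher. Nelfa (chromosome 5, 33897916 to 33936413) had 1248 ± 15 scaled reads with dTAG-13 and 1203 ± 30 with DMSO, a log2 fold change of 0.05 ± 0.30.

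The comparison of dTAG-13 with DMSO asked which transcripts differ between 2-cell embryos cultured with and without the degrader of Nelfb. Transcripts stored in the oocyte were lower in the dTAG-13 libraries, with 41 of 62 measured members lower and 1 higher, and so were genes transcribed briefly at the 2-cell stage, with 16 of 26 lower and 2 higher (2 lower and 9 higher with libraries scaled on the oocyte transcripts). Genes for ribosome assembly were higher, with 38 of 72 higher and 0 lower at an adjusted p under 0.05, and ribosomal protein genes followed with 24 of 81 higher and 1 lower. Typical members differed several-fold: the median log2 fold change was -2.38 for the oocyte transcripts and 1.76 for the ribosome assembly genes. Among 15978 genes, limma placed 1428 higher and 1565 lower in the dTAG-13 libraries at a Benjamini-Hochberg adjusted p under 0.05, so that 52.3% of the 2993 genes were lower. The smallest adjusted p was 0.0219, and 2977 of these genes had an absolute log2 fold change of at least 1.

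These counts rested on all 4 libraries. With any 1 library left out, a group has a single pool, and far fewer genes passed. Most of the lower genes that passed without a DMSO library were not among the genes lower in the main test. The median log2 fold change of all genes stayed between -0.13 and -0.08 in these fits. The balance of higher and lower genes also rested on the authors' scaling. When libraries were scaled to equal levels of the oocyte transcripts, 7081 genes were higher and 268 lower (3.65% lower), the median log2 fold change of all genes moved from -0.10 to 2.41, and 79 genes that had passed now passed in the opposite direction. When libraries were scaled to equal levels of the mitochondrially encoded genes, the median moved to 0.92 and limma called 0 genes in either direction, with 5558 at an unadjusted p under 0.05. Directions given for genes and lists are those under the authors' scaling.

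In the authors' deposited table, 1231 genes were higher and 1379 lower at an adjusted p under 0.05. Of these, 1079 were also higher and 1214 also lower in the limma test, and 0 genes passed in opposite directions. The genes with the smallest adjusted p in the authors' deposited table, named after their values were seen, were Tcl1b1 (log2 ratio -4.19), Tcl1b4 (-4.83) and Pla2g4c (-5.43).

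**Figure D1:**
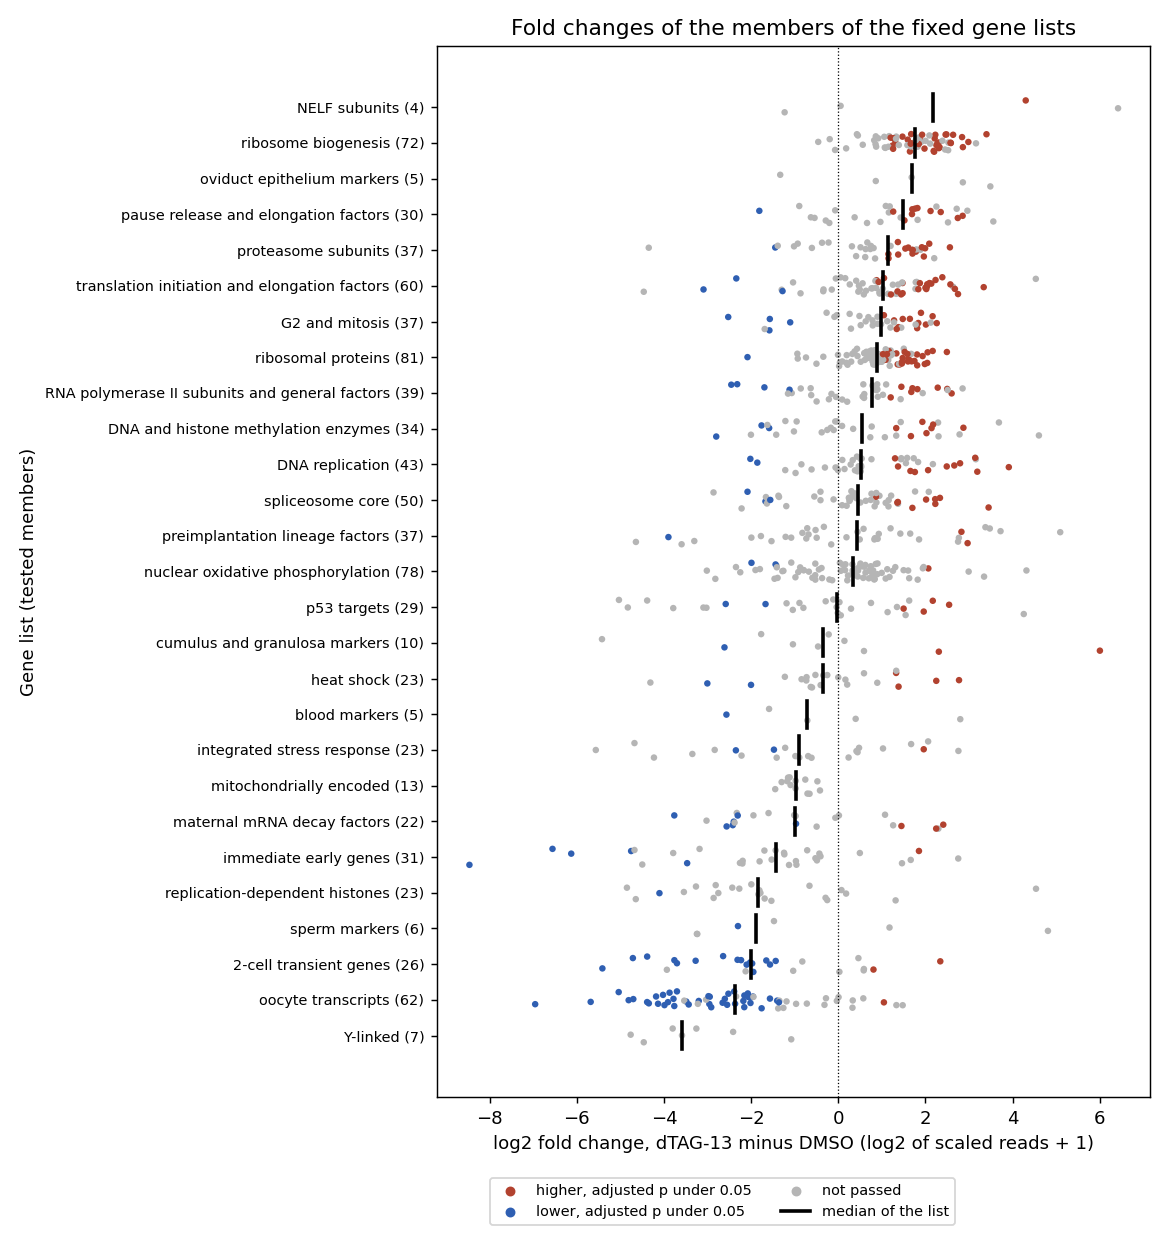
Log2 fold changes (dTAG-13 minus DMSO, horizontal axis) of the tested members of each gene list fixed beforehand (vertical axis, number of tested members in brackets), with red and blue points for genes higher or lower at an adjusted p under 0.05, grey points for the rest and a black bar at each list's median. Oocyte transcripts lie mostly to the left (median -2.38) and ribosome biogenesis genes mostly to the right (median 1.76). With libraries scaled on the oocyte transcripts the medians become 0.01, which that scaling sets, and 4.13.

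Oocyte transcripts comprised genes such as zona pellucida proteins and egg-specific regulators. The camera test placed the list below other genes (adjusted p = 2.2e-14 with the preset correlation of 0.01), and adjusted p = 0.333 with an estimated correlation. With 1 member's dTAG-13 or DMSO group at 0 set to its bound, the median stayed at -2.38. The members with the smallest p were 3 genes of the Tcl1 family and Wee2. Tcl1b2 fell by 4.81 ± 0.24 on the log2 scale, from 59933 ± 6674 to 2144 ± 367 scaled reads (adjusted p = 0.0219). Tcl1b1 fell by 4.18 ± 0.21, from 121486 ± 19755 to 6656 ± 263 scaled reads, and Tcl1b3 fell by 3.91 ± 0.22. These neighbouring, similar genes may share reads, so the split among them is uncertain. Wee2, an oocyte kinase that holds the cell cycle kinase Cdk1 inactive, fell by 3.70 ± 0.24, from 39988 ± 6969 to 3053 ± 244 scaled reads. Ccnb1, which encodes cyclin B1, was the 1 member that rose, by 1.05 on the log2 scale, and was named after its value was seen. With p adjusted over the list alone, 44 members were lower and 3 higher. Without DMSO replicate 1 the list had 12 members lower, without DMSO replicate 2 it had 5, and without either dTAG-13 library it had 0, while its median stayed between -2.62 and -2.17 and its camera adjusted p at or below 3.2e-09.

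Genes transcribed transiently at the 2-cell stage, among them the Zscan4 and Tcstv families, had a median log2 fold change of -2.0 (0.38 with libraries scaled on the oocyte transcripts, against 2.41 for all genes). The camera adjusted p was 3.5e-05 with the preset correlation and adjusted p = 0.333 with an estimated correlation. Adjusted over the list alone, 18 members were lower and 2 higher. Gm4340 fell by 5.41 ± 0.38 on the log2 scale, from 10075 ± 978 to 243.6 ± 91.0 scaled reads, and Gm5039 fell by 4.39 ± 0.36. Gm8300 fell by 1.98 ± 0.24, from 32148 ± 2448 to 8237 ± 1606 scaled reads, and Tcstv1 fell by 2.31 ± 0.28; under the oocyte scaling these 2 genes had log2 fold changes of 0.40 and 0.07. The 2 members that rose, named after their values were seen, were Tdpoz2 (2.34) and Usp17lb (0.81). Most members belong to multigene families with near-identical copies, and their individual values are uncertain. Leaving out any 1 library left 0 members past the threshold by limma, with a median between -2.10 and -1.87 and a camera adjusted p of at most 0.00283.

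Lists of genes for making and running ribosomes lay above other genes by camera with the preset correlation but did not pass with an estimated correlation, while 34 of 72 ribosome biogenesis genes and 56 of 81 ribosomal protein genes did not pass by limma. The ribosome biogenesis list had a camera adjusted p of 1.1e-16, and adjusted p = 0.439 with an estimated correlation. Lyar, a nucleolar protein, rose by 3.40 ± 0.28 on the log2 scale, from 891.8 ± 97.3 to 9466 ± 1624 scaled reads (adjusted p = 0.0219). Nip7, which acts in ribosomal RNA processing, rose by 2.98 ± 0.23, from 2990 ± 390 to 23568 ± 253 scaled reads. Wdr43, a small subunit processing factor, rose by 2.48 ± 0.26, and Nhp2, a core protein of the particles that pseudouridylate ribosomal RNA, rose by 2.25 ± 0.23. Adjusted over the list alone, 50 members were higher and 0 lower by limma; at an unadjusted p under 0.05, 58 were higher and 0 lower, and edgeR and DESeq2 also placed 0 lower. Without DMSO replicate 1 the list had 13 members higher, without DMSO replicate 2 it had 1, and without either dTAG-13 library it had 0, with a median between 1.32 and 2.00.

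Ribosomal protein genes had a median log2 fold change of 0.88 and a camera adjusted p of 1.7e-10, with adjusted p = 0.333 with an estimated correlation. Rpl4 rose by 1.61 ± 0.22 on the log2 scale, from 6490 ± 425 to 19886 ± 2290 scaled reads. Rps27l, a variant ribosomal protein gene, was the 1 member that fell, by 2.08, and was named after its value was seen. Adjusted over the list alone, 38 members were higher and 1 lower. Of 60 translation initiation and elongation factors, 22 were higher, 3 lower and 35 did not pass, with a median of 1.04 and a camera adjusted p of 5.2e-07 (adjusted p = 0.333 with an estimated correlation; 29 higher and 4 lower adjusted over the list alone). Eif4e, the factor that binds the mRNA cap, rose by 1.44 ± 0.18, from 33155 ± 1967 to 90047 ± 4419 scaled reads. Eif6, which keeps ribosomal subunits apart, rose by 3.34 ± 0.45, and Eif2s2, a subunit of the factor that delivers the initiator tRNA, rose by 2.04 ± 0.22. Of 37 proteasome subunits, 15 were higher, 1 lower and 21 did not pass (median 1.15; camera adjusted p = 9.9e-05; adjusted p = 0.439 with an estimated correlation; 18 higher and 1 lower adjusted over the list alone). Psmd12, a subunit of the regulatory particle, rose by 2.56 ± 0.31, and Psmd4, a ubiquitin receptor, rose by 1.78 ± 0.26.

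**Figure D2:**
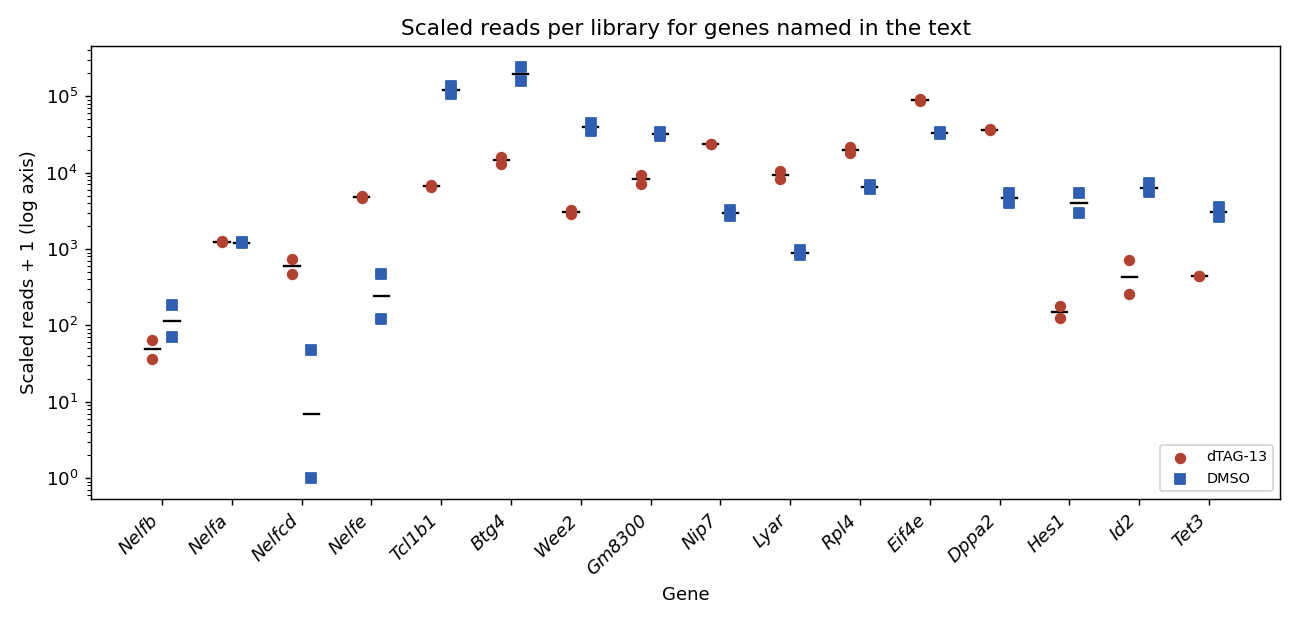
Scaled reads plus 1 (vertical log axis) in each library for 16 genes (horizontal axis), with red circles for the 2 dTAG-13 libraries, blue squares for the 2 DMSO libraries and black bars at the group means on the log scale. Nip7 lies at 23747 and 23390 scaled reads with dTAG-13 against 2714 and 3266 with DMSO, and Tcl1b1 at 6470 and 6842 against 107517 and 135455; Gm8300, lower here, lies higher with dTAG-13 when libraries are scaled on the oocyte transcripts (log2 fold change 0.40).

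Because NELF acts on RNA polymerase II, factors of pause release and elongation were examined as a group. Of 30 such genes, 10 were higher, 1 lower and 19 did not pass, with a median log2 fold change of 1.47 (camera adjusted p = 9.9e-05; adjusted p = 0.333 with an estimated correlation; 13 higher and 1 lower adjusted over the list alone). Aff1, a scaffold of the super elongation complex, rose by 2.74 ± 0.28 on the log2 scale, from 670.7 ± 73.8 to 4477 ± 6 scaled reads. Ell2, an elongation factor of the same complex, rose by 2.35 ± 0.30, and Ccnt1, the cyclin partner of the pause release kinase Cdk9, rose by 2.12 ± 0.25. Cpsf3l, the endonuclease of the Integrator complex, rose by 2.85 ± 0.33. Mllt3 was the 1 member that fell, by 1.81, and was named after its value was seen.

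Of 39 RNA polymerase II subunits and general factors, 8 were higher, 4 lower and 27 did not pass (median 0.78; 14 higher and 6 lower adjusted over the list alone). Taf1, the largest subunit of TFIID, rose by 2.50 ± 0.27 on the log2 scale and Gtf2h1, a subunit of TFIIH, rose by 2.28 ± 0.25, whereas Gtf2a2, the small subunit of TFIIA, fell by 2.46 ± 0.32. The camera adjusted p was 0.0319, and adjusted p = 0.333 with an estimated correlation; it was 0.117 without DMSO replicate 1 and 0.0626 without DMSO replicate 2. The call was also lost at means of at least 50 (0.0801) and 100 (0.118), under quantile normalization (0.229) and without a variance trend (0.0548). Of 50 core spliceosome genes, 9 were higher, 3 lower and 38 did not pass (median 0.46; 9 higher and 4 lower adjusted over the list alone). Snrpc and Snrpa, proteins of the U1 particle, rose by 2.22 ± 0.22 and 2.33 ± 0.26. The camera adjusted p was 0.0398, with adjusted p = 0.333 with an estimated correlation and 0.117 without DMSO replicate 1. It was also above 0.05 with DESeq2 (0.0588), at means of at least 50 (0.0899) and 100 (0.125), under quantile normalization (0.208) and without a variance trend (0.0905).

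Cell cycle genes moved in both directions. Of 43 DNA replication genes, 11 were higher, 2 lower and 30 did not pass (median 0.52, 0.49 to 0.90 with 1 library left out). The camera adjusted p was 0.00155, and 0.444 with an estimated correlation. Adjusted over the list alone, 16 were higher and 2 lower. This list and that of G2 and mitosis had far fewer higher members whenever 1 library was left out. Gins3 and Cdc45, parts of the replicative helicase, rose by 3.91 ± 0.60 and 2.79 ± 0.49 on the log2 scale, and Cdt1, which licenses origins, rose by 2.49 ± 0.43. Dbf4, the activator of the kinase Cdc7, fell by 2.02 ± 0.25 (0.36 under the oocyte scaling). Of 37 genes of G2 and mitosis, 12 were higher, 4 lower and 21 did not pass (median 0.98, 0.62 to 1.23 with 1 library left out; camera adjusted p = 0.000488; adjusted p = 0.396 with an estimated correlation; 16 higher and 5 lower adjusted over the list alone). Aurka, a spindle kinase, rose by 2.26 ± 0.26, from 3012 ± 444 to 14449 ± 2499 scaled reads, and Prc1, a protein of the spindle midzone, rose by 2.16 ± 0.29. Nuf2, a kinetochore protein, fell by 2.53 ± 0.36.

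Genes of mitochondria and chromatin packaging gave few single calls under the authors' scaling. Under the oocyte scaling 8 of 13 mitochondrially encoded genes were higher, as were 55 of 78 nuclear genes of oxidative phosphorylation. Of the 13 mitochondrially encoded genes, 0 passed by limma, also adjusted over the list alone. All 13 fold changes were negative, with a median of -0.98 (-1.39 to -0.58 with 1 library left out, 1.40 under the oocyte scaling), and mt-Nd1 had 253576 and 222756 scaled reads with dTAG-13 against 399594 and 645441 with DMSO. At an unadjusted p under 0.05, 6 of the 13 were lower. The count tools differed: edgeR placed 0 and DESeq2 placed 6 lower at an adjusted p under 0.05. The camera adjusted p for this list was 0.0037, with adjusted p = 0.608 with an estimated correlation and 0.12 without dTAG-13 replicate 2. It was 0.351 under quantile normalization, 0.201 under the oocyte scaling and 0.355 when scaled on these genes themselves. All genes with a symbol starting with mt-, a set not restricted to these 13, took 6.99% and 5.76% of reads in the dTAG-13 libraries. In the DMSO libraries they took 8.12% and 10.9%. The 10 most abundant genes took 8.57% and 7.81% with dTAG-13 against 12.6% and 16.5% with DMSO. Of 78 nuclear genes of oxidative phosphorylation, 1 was higher, 2 were lower and 75 did not pass (median 0.33, 0.22 to 0.40 with 1 library left out; camera adjusted p = 0.50; 0 in either direction by limma adjusted over the list alone, with 8 higher and 10 lower at an unadjusted p under 0.05). Ndufa9 rose by 2.07 ± 0.31, and Cox6b2 and Ndufa4 fell by 1.99 ± 0.37 and 1.44 ± 0.33 (0.39 and 0.94 under the oocyte scaling). Of 23 replication-dependent histone genes, 0 were higher, 1 was lower and 22 did not pass (median -1.83, -2.79 to -1.52 with 1 library left out, or 0.40 under the oocyte scaling; camera adjusted p = 0.0285; adjusted p = 0.333 with an estimated correlation; 0 by limma adjusted over the list alone, with 1 higher and 7 lower at an unadjusted p under 0.05, and 0 by edgeR and 3 lower by DESeq2). Hist1h3f fell by 4.10 ± 1.00, from 109.4 ± 10.1 to 5.70 ± 2.79 scaled reads, in libraries of polyadenylated RNA, which most replication-dependent histone mRNAs are not. The camera call for histones was lost with edgeR (adjusted p = 0.216), DESeq2 (0.264), a mean of at least 50 (0.156) and quantile normalization (0.0919).

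Lists of signal and stress responses were examined next. Of 31 immediate early genes, 5 were lower, 1 higher and 25 did not pass, with 5 lower and 1 higher adjusted over the list alone and a median of -1.44 (0.89 under the oocyte scaling). Hes1, a target of Notch signalling, fell by 4.75 ± 0.46 on the log2 scale, from 4187 ± 1776 to 149.5 ± 37.2 scaled reads, and Klf10, a factor induced by TGF-beta, fell by 3.47 ± 0.58. Fos fell by 6.56 ± 1.23, from 400.3 ± 111.0 to 5.19 ± 6.46 scaled reads, and Cyr61, a secreted matrix protein, was at least 178-fold lower. The camera adjusted p was 0.00544, with adjusted p = 0.333 with an estimated correlation and 0.0507 without DMSO replicate 1. Of 29 p53 targets, 4 were higher, 2 lower and 23 did not pass, with 4 higher and 2 lower adjusted over the list alone. Apaf1 and Sesn2 rose by 2.17 ± 0.37 and 1.96 ± 0.33, and Plk2 and Rrm2b fell by 2.58 ± 0.51 and 1.67 ± 0.25 (Rrm2b was at 0.71 under the oocyte scaling). The camera adjusted p for p53 targets was 0.965 and its direction was up, while the median was -0.04 (-0.26 to 0.12 with 1 library left out) and the mean -0.47. Of 23 heat shock genes, 4 were higher, 2 lower and 17 did not pass (median -0.35, -0.35 to -0.19 with 1 library left out; camera adjusted p = 0.80; 4 higher and 3 lower adjusted over the list alone). The cochaperones Stip1 and Fkbp4 rose by 2.25 ± 0.30 and 2.77 ± 0.50, whereas Dnajb4 fell by 3.0 ± 0.45. Of 23 genes of the integrated stress response, 1 was higher, 2 were lower and 20 did not pass (median -0.90, -0.93 to -0.58 with 1 library left out; camera adjusted p = 0.385; 1 higher and 2 lower adjusted over the list alone). Those lower were Shmt2 (fell by 2.35 ± 0.39) and Mthfd2 (fell by 1.48 ± 0.27), mitochondrial enzymes of folate metabolism, which lay at 0.02 and 0.90 under the oocyte scaling.

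Among developmental regulators, 2 of 37 preimplantation lineage factors were higher, 1 was lower and 34 did not pass. With edgeR 2 were higher and 1 lower, and with DESeq2 8 were higher and 1 lower. The median was 0.44, or 0.27 to 0.97 with 1 library left out and 0.19 with DESeq2. The camera adjusted p was 0.372, and 2 were higher and 1 lower by limma adjusted over the list alone. Dppa2 and Dppa4, partner proteins that activate 2-cell stage genes, rose by 2.97 ± 0.25 and 2.83 ± 0.54 on the log2 scale; Dppa2 went from 4731 ± 1064 to 36525 ± 1082 scaled reads. Id2, an inhibitor of helix-loop-helix factors, fell by 3.90 ± 0.56. Of 34 DNA and histone methylation enzymes, 7 were higher, 3 lower and 24 did not pass (median 0.54, 0.28 to 0.59 with 1 library left out; camera adjusted p = 0.249; 8 higher and 6 lower adjusted over the list alone). Setd2, a histone methyltransferase that travels with elongating polymerase, rose by 2.02 ± 0.23, and Kdm4c, a histone demethylase, rose by 2.87 ± 0.33. Tet3, the dioxygenase that oxidizes methylated cytosine in the zygote, fell by 2.80 ± 0.33, from 3106 ± 651 to 440.0 ± 2.1 scaled reads. Of 22 factors of maternal mRNA decay, 3 were higher, 6 lower and 13 did not pass (median -0.99, or 1.37 under the oocyte scaling; camera adjusted p = 0.143, or 0.0496 with edgeR; 5 higher and 7 lower adjusted over the list alone). Btg4, an adaptor of the CCR4-NOT deadenylase in the egg that was also in the oocyte list, fell by 3.76 ± 0.29, from 201413 ± 62521 to 14571 ± 2408 scaled reads. Cnot7 and Cnot6l, deadenylase subunits, fell by 2.42 ± 0.22 and 2.56 ± 0.32, while Cnot1, the scaffold of the same complex, rose by 2.41 ± 0.30.

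Markers of other cells and of embryo sex were read as a check on the pools. Of 10 detected cumulus and granulosa markers, 2 were higher (Amhr2 and Star), 1 was lower (Serpine2) and 7 did not pass (median -0.34, or 1.34 without DMSO replicate 1 and -1.86 without DMSO replicate 2; camera adjusted p = 0.933; 2 higher and 2 lower adjusted over the list alone). Star had 44.2 and 90.0 scaled reads with dTAG-13 and no read with DMSO, at least 15.8-fold higher. Of 6 sperm markers, 1 was lower, Odf2, which fell by 2.30 ± 0.37 (0.08 under the oocyte scaling), and 5 did not pass. Adjusted over the list alone, 1 was lower. At an unadjusted p under 0.05 by limma, 2 were higher, Akap3 and Ldhc, and 1 was lower. The median of the sperm markers was -1.89, or -0.56 at means of at least 50, and their camera adjusted p was 0.639. Among 5 oviduct epithelium markers, 0 passed by limma or edgeR, 1 was higher at an unadjusted p under 0.05 and by DESeq2, and Epcam was the most abundant at 7299 ± 534 with dTAG-13 and 4019 ± 264 scaled reads with DMSO (list median 1.68, 0.79 to 2.54 with 1 library left out, 0.89 with edgeR and 0.86 with DESeq2; camera adjusted p = 0.377; 0 by limma adjusted over the list alone). Of 5 blood markers, 1 was lower, Hba-a1, which fell by 2.57 ± 0.41 from 1051 ± 15 to 178.1 ± 34.0 scaled reads, and 4 did not pass (median -0.71, -1.0 to 0.27 with 1 library left out; camera adjusted p = 0.484; 1 lower adjusted over the list alone). Of the 7 Y-linked genes, 0 passed by limma (also adjusted over the list alone), edgeR or DESeq2, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.218). Eif2s3y had 1177 scaled reads in dTAG-13 replicate 1, 0 in dTAG-13 replicate 2, and 1565 and 365.2 in the DMSO libraries. Ddx3y, Usp9y and Zfy2 also had 0 in dTAG-13 replicate 2 and had reads in every other library. The pool of dTAG-13 replicate 2 thus showed no sign of a male embryo in these genes. The list's median of -3.59 became 0.64 without dTAG-13 replicate 2 and -7.19 without dTAG-13 replicate 1. It was -0.76 with edgeR and -0.78 with DESeq2.

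The largest changes among genes with a mean of at least 100 scaled reads were mostly between a group with over 100 scaled reads and a group without any read. For such genes a bound was computed from a floor of 3 reads per library. Pmm2, a phosphomannomutase of protein glycosylation (chromosome 16, 8637674 to 8662467), had 600.3 and 592.1 scaled reads with dTAG-13 and none with DMSO, at least 141-fold higher (adjusted p = 0.0219). Gorasp1, a Golgi stacking protein (chromosome 9, 119925257 to 119937565), was at least 149-fold higher, and Serping1, the inhibitor of complement C1 (chromosome 2, 84765387 to 84775444), at least 135-fold higher. Tmem229b was at least 63.9-fold higher, Adat3, a subunit of a tRNA adenosine deaminase, at least 57.5-fold, Fancf, a gene of a single annotated exon in the Fanconi anaemia repair pathway, at least 54.0-fold, Fancd2os at least 51.6-fold and Zfp771 at least 50.7-fold. Exons of other genes covered 71.9% of the exonic bases of Adat3, and the library was not stranded, so its reads may belong to a neighbour. Abhd17a and Coro1a had 1 read in DMSO replicate 2; their ratios were 733 (95% counting interval 131 to 28974) and 406 (72.7 to 16067).

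In the other direction, Rnf5, a membrane-bound ubiquitin ligase (chromosome 17, 34601091 to 34603690), had 708.5 and 1536 scaled reads with DMSO and none with dTAG-13, at least 567-fold lower (adjusted p = 0.0219). Magea10 (chromosome X, 72381870 to 72386858) was at least 255-fold lower, Rab32, a small GTPase (chromosome 10, 10545002 to 10558265), at least 225-fold lower, and Plcxd2 at least 207-fold lower. Car10 was at least 167-fold, Rasgef1b at least 164-fold, Lancl2 at least 153-fold and Tpp1, a lysosomal peptidase, at least 150-fold lower. Fam90a1a had 1 read in dTAG-13 replicate 2 and a ratio of 1688 (95% counting interval 302 to 66750). In all, 35 genes had no read in either dTAG-13 library and at least 100 scaled reads in both DMSO libraries, and 20 genes had the opposite pattern. Within a group, 97 genes had no read in 1 dTAG-13 library and at least 100 scaled reads in the other, and 224 genes did so between the DMSO libraries. Intervals and floors cover counting error only.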

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

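Thinning to the smallest depth was chosen after the data were seen; all other alternatives were fixed beforehand. Against 1428 genes higher and 1565 lower (52.3% lower) in the main test, edgeR gave 1026 and 1146, of which 1026 and 1144 were the same genes, and thinning gave 1392 and 1547. DESeq2 gave 2406 and 2650, and an adjusted p under 0.1 gave 2583 and 2859. Without a variance trend limma called 209 and 380 (64.5% lower); the cause was not tested. Scaling on the oocyte transcripts gave 7081 and 268 (3.65% lower) because it raised the median of all genes to 2.41. Scaling on the mitochondrially encoded genes gave 0 and 0 by limma, with 5558 genes at an unadjusted p under 0.05. Under the authors' scaling the mitochondrial list differed between replicates (1 minus 2) by a median of -0.79 for DMSO and 0.35 for dTAG-13. Equalizing that list passes these shifts on to every gene, which widens the spread between replicates. Whether this alone removed the calls was not tested. Leaving out 1 library, so that a lone pool is assumed to vary like the other group, gave 0 to 323 higher and 0 to 701 lower genes: 0 and 0 without dTAG-13 replicate 1 (3538 at an unadjusted p under 0.05) or replicate 2 (3906), 323 and 701 without DMSO replicate 1, and 35 and 565 without DMSO replicate 2. The share lower was then 68.5% to 94.2%, with no value where 0 genes passed. Under the remaining alternatives both counts stayed within 1.5 times the main counts, and Nelfb did not pass under any alternative that tested it (a mean of at least 100 left it out). The replicate block gave 1855 and 1832; the labels share only numbers, and the deviations of same-numbered libraries correlated across genes at r = -0.014. With the block the camera adjusted p of the histone and spliceosome lists was 0.0596 each, and no other list call changed. Camera calls of the histone, spliceosome, RNA polymerase II, mitochondrially encoded and immediate early lists were each lost under at least 1 other alternative, and those of the other 9 lists that passed were lost only with an estimated correlation. Fits with a library left out aside, some lists passed camera only under an alternative. Maternal mRNA decay factors did so with edgeR (0.0496), and Y-linked genes when scaled on mitochondrially encoded genes (0.0351). Oxidative phosphorylation, heat shock, methylation enzymes and Y-linked genes did so under the oocyte scaling (0.00242, 0.00585, 0.00388 and 0.0018). The named Y-linked genes had no read in dTAG-13 replicate 2, so the passes of that list may reflect 1 pool. Under the oocyte scaling these log2 fold changes turned among named genes past the threshold under either scaling: Gm8300 0.40, Tcstv1 0.067, mt-Nd1 1.28, mt-Nd2 1.40, mt-Nd4 1.62, Cox6b2 0.39, Ndufa4 0.94, Dbf4 0.36, Rrm2b 0.71, Shmt2 0.024, Mthfd2 0.90, Odf2 0.076 and Cd74 1.67. Among named genes that passed under neither, Nelfb (1.11), mt-Co3 (1.23), Ndufb8 (0.91), Slc7a11 (0.96) and Tppp3 (1.03) turned. The medians that turned were those of 2-cell genes (0.38), oocyte transcripts (0.0091), maternal decay factors (1.37), mitochondrially encoded genes (1.40), histones (0.40), p53 targets (2.37), immediate early genes (0.89), heat shock (2.08), the integrated stress response (1.46) and markers of cumulus (2.33), sperm (0.83) and blood (1.67). All moved with the shift of all genes. The oocyte list was scaled on itself here, so its median near 0 was set by the scaling. Under other alternatives medians turned only for lists that did not pass camera in the main test (p53 targets, heat shock, the integrated stress response, Y-linked genes and markers of cumulus, oviduct and blood). Depth limits genes with few reads: 3 reads in a library are 1.87 to 4.87 scaled reads.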

Other observations

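Of the tests below, those of developmental progress, exchanged labels, GC content, transcript length and independent loss were chosen after the result was seen. Long genes formed a group not described above. Among 8747 protein-coding genes with a mean of at least 100 scaled reads, the 875 with annotated spans over 129 kb had a median log2 fold change of -1.42, against 0.30 for the others, and 209 of them were lower and 39 higher at an adjusted p under 0.05 by limma. Over 10 classes of span with similar numbers of genes, the median lay between 0.31 and 0.55 in the 7 classes up to 50.7 kb, and was -0.01 at 50.7 to 75.0 kb, -0.43 at 75.1 to 129 kb and -1.42 beyond. Among the long genes with the smallest p, named after their values were seen, were Chn1 (164.7 kb, log2 fold change -3.94 ± 0.34), Fbxl17 (442.6 kb, -3.06 ± 0.31), Suclg2 (245.8 kb, -3.56 ± 0.38), Obox1 (167.9 kb, -3.76 ± 0.40; a family with similar copies), Sorbs2 (320.1 kb, -3.79 ± 0.41) and, in the other direction, Aff1 (162.9 kb, 2.74 ± 0.28). The class with the longest spans held 0 of the 58 oocyte transcripts in this set, so these are different genes from the fixed oocyte list.

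For the lower level of long genes, the difference in median between these 875 genes and the rest was negative in all 4 pairs of a dTAG-13 with a DMSO library, from -1.90 to -1.21. The tables argue against GC content as the whole cause, since the difference was -0.97 or further below 0 in each of 5 GC classes. Fold changes did vary with GC content, however. The median log2 fold change of the other genes rose from -0.30 in the class with the lowest GC content to 0.90 in the highest. Whether GC content contributed to the medians of the gene lists was not tested. Low-level background reads do not account for it either, since it was -1.65 among 3537 genes with a mean of at least 1000 scaled reads. Transcript length was likewise set aside: the smallest difference over 5 classes was -0.75, in a class with 13 long genes, and the others lay between -2.25 and -1.55. It remains open whether an effect of the degrader on transcription across long genes or a different mix of maternal and embryonic transcripts may underlie the pattern; the DMSO libraries also differed from each other (-0.45, replicate 1 minus replicate 2), and no biological explanation was tested.

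Lower oocyte transcripts together with higher ribosome biogenesis genes are the pattern that embryos further along in clearing maternal RNA could show, and this direction for embryos that were given a degrader of NELF is one to look at again. The tables argue against depth: with all libraries thinned to the smallest total, the gap between the 2 medians was 4.13 on the log2 scale, against 4.14 at full depth. Pools at different developmental progress remain a candidate explanation. The 2 DMSO pools differed along the same axis by 1.17 and the 2 dTAG-13 pools by 0.25, which are 28.2% and 6.01% of the gap between groups. The 95% ranges of 10000 random matched lists were -0.34 to 0.35 and -0.16 to 0.15. Random lists were matched on mean level only, whereas members of the real lists moved together. Their estimated correlations were 0.463 for ribosome biogenesis and 0.215 for oocyte transcripts. The ranges leave this out and cannot judge the differences between pools. A difference in progress may come from the treatment or from the embryos pooled, and 2 pools per group cannot separate these. An exchange of all group labels cannot be told apart from an effect, because no measured value marks the treatment itself and Nelfb mRNA (log2 fold change -1.23) is not the target of the degrader.

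In all, 55 genes had no read in both libraries of 1 group and at least 100 scaled reads in both of the other, 35 absent with dTAG-13 and 20 absent with DMSO. At the rates of loss seen within groups at the same abundance, 0.242 such genes were expected from independent loss in single libraries, 0.44% of the number observed. This expectation takes genes of similar abundance as equally prone to loss. Genes that are individually prone to loss would give more such cases, and this was not tested. A difference between the groups in whether these genes were transcribed or retained may underlie some of them. The treatment and any other difference between the pools remain open. Reads shared with overlapping genes were not tested for this set.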
